A study of Homo sapiens with 18 samples.

How the data were processed

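The study measured transcripts of the human embryonic stem cell line H1 on 18 Affymetrix Human Gene 1.0 ST arrays. The labels name 6 groups of 3 arrays, formed by 2 states and 3 treatments. The states are pluripotent cells, kept without feeders on Matrigel in mTeSR1 medium, and embryoid bodies, made in AggreWell plates and grown in APEL medium for 6 days. The treatments are no transduction, a lentivirus with a control shRNA, and a lentivirus with an shRNA against KBTBD8. RNA was purified with RNeasy columns and labelled with NuGEN kits. The labels do not say whether the 3 arrays of a group came from separate cultures, so every p-value here measures spread between arrays, which may be technical.

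The deposited values are log2 intensities made by the authors with GCRMA, per the submitters' processing notes, which give no version. The log base is not stated and was taken from the method and from the range of the values. The notes also do not say whether all 18 arrays were normalized together. Raw array files were not analysed here, so background correction and summarization were not repeated. On arrays the only statement made about depth is that their number limits the precision.

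The array table held 33297 probe sets. Of these, 19460 carried exactly 1 gene symbol, 1754 carried several and 12083 carried none. Probe sets with 1 symbol covered 18417 genes, and the 1 with the highest mean over the 18 arrays stood for its gene. Symbols were brought to current names with the RefSeq annotation of GRCh38.p14, where 31 had no entry, and no coordinates were used. Genes whose probe sets all carry several symbols, such as POU5F1 and NANOG, were not analysed here as genes. A gene was tested when it lay above the 40th percentile of the array on at least 3 arrays, which left 14209 genes. Probe sets without exactly 1 symbol were fitted separately and only counted, without reading them as genes.

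Each gene was fitted with limma 3.58.1 in R 4.3.3, as 1 model with a mean for each of the 6 groups, empirical Bayes variances and 12 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over the genes tested within each comparison, and a gene is said to have risen or fallen at an adjusted p under 0.05. The comparisons, the groups, the lists, the alternatives and the rule for naming genes were written before the data were examined, except for the additions described further on. For KBTBD8 itself an exact test over all regroupings of the arrays was added. With 3 against 3 arrays its smallest possible p is 0.1. Values are log2 differences, and a range after a group mean is 1 standard deviation. After ± beside a log2 difference stands the standard error. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

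Genes were named by a fixed rule. KBTBD8 is given in every comparison. For differentiation, for both KBTBD8 comparisons and for the interaction, the 10 largest increases and the 10 largest decreases past the threshold were taken, with no overlap between the groups compared (the interaction has no such condition). Differentiation was ranked on the untransduced arrays, so control shRNA differentiation has no ranking of its own. KBTBD8 shRNA differentiation and both comparisons of control shRNA with untransduced cells name 5 and 5. A comparison added later was not ranked. From each list described, 2 to 4 members with the largest change are given. A set of 14 genes (POU5F1, NANOG, SOX2, SOX10, FOXD3, TFAP2A, SNAI2, PAX3, PAX6, SOX1, TBXT, SOX17, TCOF1 and NOLC1) is given in every comparison fixed beforehand where it was tested.

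Lists of genes were fixed from general knowledge, 27 in number with 583 members. They cover pluripotency, neural crest, neural plate, neuron, surface ectoderm and placode, primitive streak, lateral and cardiac mesoderm, endothelium and blood, endoderm, trophoblast and amnion, mesenchyme and matrix, HOX genes, ribosome biogenesis, ribosomal proteins, CUL3 adaptors, p53 targets, cell cycle, interferon response, integrated stress and unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, targets of WNT, BMP, NOTCH, FGF-ERK and retinoic acid signalling, and replication-dependent histones. A list needed at least 5 tested members. Lists were tested with camera from limma at its preset correlation of 0.01, with p adjusted over the 27 lists. They were also tested with a correlation estimated from the residuals, and this second adjusted p is given where the call was lost. Counts of members are given over all genes tested and also adjusted over the list alone.

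After the first look at the values, both arrays numbered 2 of the KBTBD8 shRNA were found to lie with the other state. The labels were kept as given in the fit of all 18 arrays. An alternative chosen after seeing the data left both out, which gives 16 arrays, 2 in each KBTBD8 shRNA group and 10 residual degrees of freedom. The genes were renamed by the same rule on the 16 arrays. A comparison of the difference in differentiation between control shRNA and untransduced arrays was likewise added after seeing the data. So was a pair of further lists, of ATF4 targets and of anterior neural genes, each written with its predicted direction before the values of its genes in the comparison were read.

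The steps were tested on simulated data with 200 changed genes in the embryoid body comparison of the shRNAs. With the labels right, 18 arrays recovered 70.1% of 67 genes changed by a log2 of 0.5, 92.5% of 67 genes changed by 1 and 98.5% of 66 genes changed by 2, with 10 false calls. The 16 arrays recovered 52.2%, 89.6% and 98.5%, with 8 false calls. When 2 KBTBD8 shRNA arrays were exchanged, the 18 arrays recovered 0%, 5.97% and 3.03%, with 0 false calls. A simulated fall of 0.5 in the neural crest list gave a camera adjusted p of 2.69e-23 and called 0 of the other lists. The simulated noise was independent between genes, so this does not test the preset correlation on genes that vary together.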

Results

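KBTBD8 is a substrate adaptor of the CUL3 ubiquitin ligase, with a role described in the formation of the neural crest. Its own level came first, because it tests the labels of the shRNA arrays. In untransduced cells KBTBD8 averaged 6.32 ± 0.25 in pluripotent cells and 4.56 ± 0.50 in embryoid bodies. With the control shRNA the means were 6.84 ± 0.39 and 4.75 ± 0.31. With the KBTBD8 shRNA they were 4.88 ± 0.30 and 4.88 ± 0.23. KBTBD8 fell by 1.96 ± 0.25 under its shRNA in pluripotent cells (adjusted p 8.6e-04, exact p 0.1), though not when only the groups compared were fitted (adjusted p 0.0938). On the arrays labelled pluripotent with this shRNA KBTBD8 lay at the 34.4, 23.5 and 32.8 percentile, in the order of their numbers. All were under the 40th used as a filter, so the fall ends at a low intensity. The lowest was on the array numbered 2, which lay with the other state. In embryoid bodies, where its level was already low, KBTBD8 did not pass the threshold (0.12 ± 0.25, adjusted p 0.88, exact p 0.6). The fall in pluripotent cells kept its direction on 16 arrays (−1.79). In embryoid bodies the difference was 0.01 on 16 arrays and ranged from −0.04 to 0.27 with 1 array left out, so its sign was not stable.

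**Figure D1:**
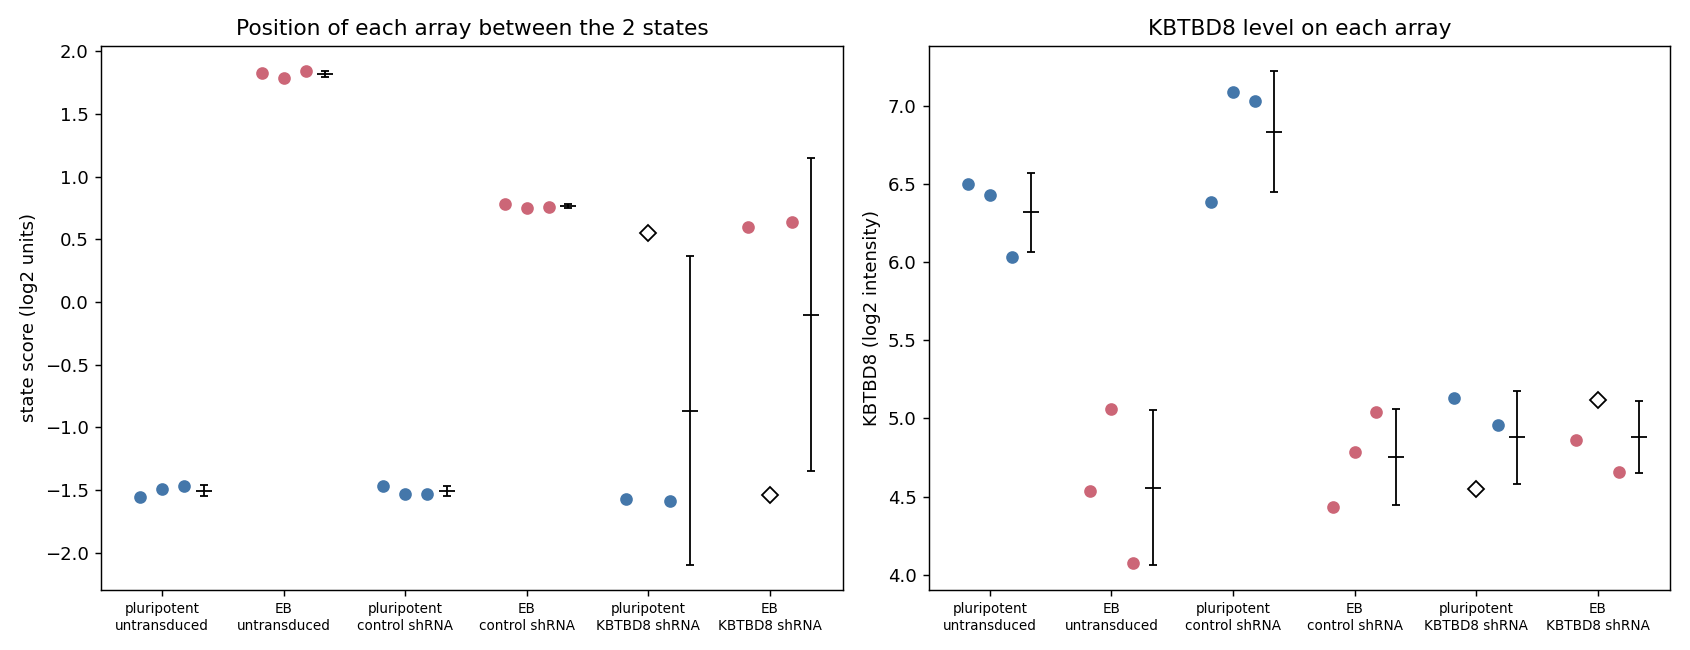
Each point is 1 array, set out by state and treatment. The left panel shows the state score in log2 units and the right panel the log2 intensity of KBTBD8; open diamonds mark both arrays numbered 2 of the KBTBD8 shRNA, and bars show the mean and 1 standard deviation of each group of 3 arrays.

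A pair of arrays did not lie with their own groups. A state score was built from 1333 genes that differed between untransduced embryoid bodies and untransduced pluripotent cells, 615 higher and 718 lower. The array labelled hESC_shKBTBD8_2 scored 0.55, whereas the other pluripotent arrays lay between −1.59 and −1.46. The array labelled EB6_shKBTBD8_2 scored −1.54, whereas the other embryoid body arrays lay between 0.60 and 1.84. That range split by treatment, with 1.79 to 1.84 untransduced, 0.75 to 0.78 with the control shRNA and 0.60 to 0.64 with the KBTBD8 shRNA. The genes of the score were chosen on the untransduced arrays, which favours a wide distance there. By correlation across genes, the pluripotent-labelled array was nearest to the KBTBD8 shRNA embryoid bodies (0.990, against 0.908 with its own group). The embryoid-body-labelled array was nearest to the pluripotent KBTBD8 shRNA arrays (0.993, against 0.914). All 16 of the other arrays were nearest to their own group. The level of KBTBD8 could not separate the labels, since under the shRNA it was alike in both states. Labels were kept as given, and results that rest on these arrays are given for 18 arrays and again for the 16 left without them.

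Differentiation for 6 days lowered many pluripotency genes and raised early neural genes. CRIPTO (a NODAL coreceptor), PODXL (a surface glycoprotein of stem cells) and the microRNA gene MIR302A fell, while PAX6, SIX3, LHX2 and DACH1, which pattern the eye and forebrain, rose. DLK1 (a NOTCH-like ligand) and IGFBP5 (a binding protein for insulin-like growth factors) were among the largest increases. In untransduced cells 5491 genes changed, 2919 higher and 2572 lower in embryoid bodies, and 1274 of them by 2-fold or more. On 16 arrays the same comparison called 7411. The 10 largest increases were DLK1 (6.65 ± 1.32, adjusted p 1.1e-03), PAX6 (5.85 ± 1.11, adjusted p 8.4e-04), IGFBP5 (5.71), LIX1 (5.36), FLRT3 (5.01), GREB1L (4.77), PRTG (4.72), DACH1 (4.60), SIX3 (4.41) and LHX2 (4.40). The 10 largest decreases were CRIPTO (−7.91 ± 1.00, adjusted p 2.8e-05), RARRES2 (−5.29), NTS (−4.92), PMAIP1 (−4.64), IDO1 (−4.61), MIR302A (−4.49), FLT1 (−4.44), PODXL (−4.34), GAL (−4.30) and CD9 (−4.28). KBTBD8 itself fell by 1.76 ± 0.25 (adjusted p 9.2e-05, exact p 0.1). Of the fixed set, SOX2 rose by 0.81, FOXD3 fell by 1.17 and TCOF1 fell by 0.56. The genes TFAP2A (1.56), SNAI2 (0.68), PAX3 (0.39), SOX1 (0.34), SOX10 (0.21), SOX17 (0.01), TBXT (−0.26) and NOLC1 (−0.33) did not pass on 18 arrays. On 16 arrays, with the same differences and smaller errors, TFAP2A, SNAI2 and PAX3 rose and NOLC1 fell.

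Members of several lists changed with differentiation, though no list passed at an estimated correlation on 18 arrays. The pluripotency list had 1 member that rose, 16 that fell and 5 that did not pass (17 fell when adjusted over the list alone), with ZFP42 at −2.78 and POLR3G at −3.60. In the neural plate list 13 of 24 members rose and none fell (13 adjusted over the list alone). Cholesterol synthesis lost 6 of 13 members (8 adjusted over the list alone), among them SC5D (−1.53) and MVD (−0.90). The stress response list lost 8 of 16 members (8 adjusted over the list alone), with VLDLR and CHAC1 both at −2.13 and ASNS at −1.91. Among CUL3 adaptors 12 of 21 rose and 1 fell (12 and 1 adjusted over the list alone), with IPP at 1.15 and KLHL20 at 0.84. Ribosome biogenesis lost 15 of 53 members while 3 rose (15 and 3 adjusted over the list alone), with DDX21 at −1.29 and MYBBP1A at −0.92. Ribosomal proteins gained 6 of 56 (3 adjusted over the list alone), with RPL32 at 0.63 and RPL22 at 0.52. These 7 lists passed camera at the preset correlation. None did at an estimated correlation (adjusted p 0.58 to 0.81), where 3 passed on 16 arrays. Both out-of-place arrays are not part of this comparison, but their spread enters its errors and estimated correlations on 18 arrays. PAX6 had standard deviations of 0.22 and 0.07 in the untransduced groups, against 2.57 and 2.73 in the KBTBD8 shRNA groups. Without those arrays the pluripotency list moved from a camera adjusted p of 0.62 to 0.0061 at an estimated correlation.

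In control shRNA cells neural crest genes rose along with neural ones. SNAI2, a zinc finger factor of migrating crest, and SOX10, a marker of crest progenitors, rose, as did PAX3 and TFAP2A of the neural plate border. In this comparison 4810 genes changed, 2431 higher and 2379 lower, 1007 of them by 2-fold or more (6866 on 16 arrays). Across genes the changes correlated at 0.76 with those of untransduced cells. Both treatments shared 1639 genes that rose (499 if the calls were independent) and 1396 that fell (431), and 87 genes moved in opposite directions. The fixed set gave TFAP2A 4.45, PAX6 5.02, PAX3 4.54, SNAI2 4.41, SOX10 2.21 and FOXD3 0.95, all of which rose, while TCOF1 (−0.55) and NOLC1 (−0.55) fell. SOX2 (0.00), SOX1 (0.09), TBXT (−0.10) and SOX17 (−0.12) did not pass. KBTBD8 fell by 2.08 ± 0.25 (adjusted p 6.4e-05, exact p 0.1).

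Among lists in the control shRNA cells, neural crest had 14 of 20 members that rose and 0 that fell (16 rose adjusted over the list alone), with TFAP2B at 5.70. This list came from textbooks, and published work on these samples concerns the crest, so it is not independent of that work. Neurons gained 8 of 11 members (8 adjusted over the list alone), with MAP2 at 2.74 and STMN2 at 2.15. The neural plate list gained 9 of 24 (10 adjusted over the list alone), with EMX2 at 3.21 and DACH1 at 2.66. Hypoxia and glycolysis gained 12 of 18 and lost 1 (13 and 1 adjusted over the list alone), with ANKRD37 at 3.19, NDRG1 at 2.86 and BNIP3 at 2.64. WNT targets gained 4 of 9 (5 adjusted over the list alone), namely LEF1 (3.65), DKK1 (3.52) and AXIN2 (1.48) among them. Losses came in pluripotency (14 of 22, GDF3 −2.87), cholesterol synthesis (10 of 13, DHCR7 −1.45, SQLE −1.12), cell cycle (16 of 27, MCM5 −0.95), ribosome biogenesis (33 of 53, LYAR −1.36, NOP16 −1.29) and FGF-ERK targets (7 of 14, DUSP6 −2.69, ETV4 −1.74). Adjusted over the list alone the losses were 14, 10, 16, 34 and 7. In the same lists 1, 0, 4, 3 and 2 members rose (2, 0, 4, 3 and 2 adjusted over the list alone). With the ribosomal proteins, 11 lists passed camera at the preset correlation and none at an estimated one (adjusted p 0.08 to 0.60), where 6 passed on 16 arrays, the neural crest among them.

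Differentiation under the KBTBD8 shRNA could be read only on the 16 arrays. SIX3 of the forebrain and DLX5 of the placodes were among the largest increases there, and CRIPTO was again among the largest decreases. With all 18 arrays no gene passed, and 763 had an unadjusted p under 0.05. On 16 arrays 5465 genes changed, 2464 higher and 3001 lower. The 5 largest increases were PRTG (5.47, against 1.996 on 18 arrays), DLX5 (5.37, 1.89), DLK1 (5.24, 1.64), GREB1L (5.23, 1.78) and SIX3 (5.03, 1.72). The 5 largest decreases were ADCY2 (−4.54, −1.46), ERVH48-1 (−4.20, −1.43), INHBE (−4.19, −1.75), CRIPTO (−3.99, −1.28) and FLT1 (−3.93, −1.30). KBTBD8 did not pass on either count (0.00 and −0.28). Of the fixed set on 16 arrays, with 18 second, PAX6 (4.61, 1.56), TFAP2A (4.11, 1.45), PAX3 (3.02, 1.08), SNAI2 (1.98, 0.53), SOX10 (0.61, 0.25), SOX17 (0.40, 0.16) and SOX2 (0.31, 0.088) rose and NOLC1 (−0.42, −0.006) fell. FOXD3 (−0.37, −0.18), SOX1 (0.33, 0.14), TBXT (0.10, 0.026) and TCOF1 (−0.26, 0.047) did not pass. On all 18 arrays 6 lists passed camera at the preset correlation and none at an estimated one; on 16 arrays 11 and 8 did.

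Before differentiation, control shRNA cells differed from untransduced ones in genes of varied function, and endoderm was the only list to pass at both correlations. CST1, a secreted cystatin, and FN1, the matrix protein fibronectin, rose together with ANKRD1, a target of YAP signalling. TXNIP, an inhibitor of thioredoxin, and DDIT4, an inhibitor of mTOR, fell. In pluripotent cells 1713 genes changed, 985 higher and 728 lower, 68 of them by 2-fold or more (4132 genes on 16 arrays, 2644 with only the groups compared, and as few as 856 without 1 array). The largest increases were CST1 (3.67), SNORD13P1 (2.10), ANKRD1 (1.92), FN1 (1.76) and SNORD75 (1.75). The largest decreases were H2BC12 (−3.31), TXNIP (−1.88), EGR1 (−1.72), DDIT4 (−1.64) and SCARNA14 (−1.58). KBTBD8 did not pass (0.52 ± 0.25, adjusted p 0.20, exact p 0.3). Of the fixed set SOX17 (0.43) and TCOF1 (0.51) rose, and SOX2 (−0.20), SOX10 (0.23), FOXD3 (−0.070), TFAP2A (0.55), SNAI2 (0.25), PAX3 (0.40), PAX6 (0.13), SOX1 (−0.18), TBXT (0.20) and NOLC1 (0.21) did not pass, of which TFAP2A and PAX3 did on 16 arrays. The endoderm list had 7 of 14 members that rose (8 adjusted over the list alone), with APOA2 at 1.70, AFP at 1.68 and TTR at 1.55, and it passed camera at both correlations (adjusted p 3.6e-05 and 0.0066). Targets of p53 lost 6 of 22 members (8 adjusted over the list alone), with FAS at −1.12, but lost the call at an estimated correlation (adjusted p 0.36). In the same way ribosome biogenesis (adjusted p 0.96), ribosomal proteins (0.96) and histones (0.63) passed at the preset correlation alone.

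After differentiation many crest, surface ectoderm and endoderm genes were higher in control shRNA than in untransduced embryoid bodies. At an estimated correlation only the endoderm list kept its call on 18 arrays (adjusted p 0.0087, against 0.16 for crest and 0.28 for surface ectoderm). TFAP2B, PAX3 and ETS1 belong to the crest, CDH1 and EPCAM to epithelium, and AFP and TTR to liver and yolk sac. FGF9 and the forebrain gene LHX2 were lower. In embryoid bodies 3850 genes changed, 2130 higher and 1720 lower, 499 by 2-fold or more (6370 on 16 arrays, 7046 with only the groups compared, and as few as 2446 without 1 array). The largest increases were TFAP2B (4.95), PAX3 (4.55), DKK1 (4.51), CDH9 (4.30) and ETS1 (4.07), and the largest decreases FGF9 (−3.08), LHX2 (−2.96), PRSS23 (−2.77), IGFBP3 (−2.60) and ME3 (−2.45). In the crest list 14 of 20 rose and none fell (16 adjusted over the list alone), including SNAI2 (3.98), TFAP2A (3.44), SOX10 (2.22) and FOXD3 (2.05). SOX2 fell by 1.02, TCOF1 rose by 0.52 and TBXT rose by 0.36. PAX6 (−0.70), SOX1 (−0.43) and SOX17 (0.31) passed only on 16 arrays, and NOLC1 (−0.013) and KBTBD8 (0.20 ± 0.25, exact p 0.7) did not pass. Surface ectoderm gained 6 of 13 (7 adjusted over the list alone), with CDH1 at 3.48 and EPCAM at 2.75. During differentiation itself 1 member of this list rose and 4 fell in untransduced cells, and 3 rose and 3 fell with the control shRNA. It passed camera in neither (adjusted p 0.11 and 0.71), so its higher level here does not show a gain of surface ectoderm. Endoderm gained 7 of 14 and lost 1 (8 and 1 adjusted over the list alone), with AFP at 3.71, APOA2 at 3.26 and TTR at 2.94. Lateral and cardiac mesoderm gained 3 of 7 (3 adjusted over the list alone), with MEF2C at 2.64, and retinoic acid targets gained 3 of 6 (3 adjusted over the list alone), with CYP26A1 at 2.45. Trophoblast and amnion gained 4 of 8 and lost 1 (5 and 1 adjusted over the list alone). Of 13 lists that passed camera, the 12 besides endoderm lost the call at an estimated correlation (adjusted p 0.16 to 0.68), and on 16 arrays 6 passed, crest included (adjusted p 1.7e-04). Genes moved alike in both states by this contrast, with a correlation of 0.42, 535 shared rises (148 if independent) and 411 shared falls (88.1). No array separates an effect of the virus from other differences between untransduced and transduced cultures. The control shRNA embryoid bodies also stood lower on the state score (0.75 to 0.78, against 1.79 to 1.84 untransduced). The genes of that score were chosen on the untransduced arrays, which favours a wide distance there. The lower score thus cannot show whether their position between the states differed as well.

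Pluripotent cells with the KBTBD8 shRNA had lower levels of sterol synthesis genes and higher levels of single genes that respond to stress or nutrients. The stress response list itself did not pass on 18 arrays (camera adjusted p 0.60) and did on 16 (5.2e-04). TXNIP and its relative ARRDC4 restrain glucose uptake, DDIT4 restrains mTOR, and DDIT3 is a transcription factor of the stress response; all of them rose. The secreted cystatin CST1 fell the most, and so did the replication genes RRM2 and FAM111B and the liver and yolk sac genes TTR, APOA2 and AFP. On 18 arrays 729 genes changed, 326 higher and 403 lower, 37 of them by 2-fold or more, and 2710 genes had an unadjusted p under 0.05. The count depended on the fit, with 0 genes when only the groups compared were fitted, 310 with a replicate block and 294 to 657 with 1 array left out. On 16 arrays 1991 changed, 1198 higher and 793 lower, and both fits shared 692.

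The 10 largest increases in pluripotent cells on 18 arrays, with 16 arrays second, were TXNIP (3.15 ± 0.31, adjusted p 1.3e-04; 3.53), DDIT4 (1.94, 1.70), ARRDC4 (1.79, 2.43), TFAP2C (1.56, 1.12), DDIT3 (1.49, 1.94), VEGFA (1.38, 1.39), C14orf39 (1.36, 1.47), ZMAT1 (1.26, 1.46), LGALS1 (1.25, 1.11) and SLC9B1 (1.22, 0.85, the last not passing). The 10 largest decreases were CST1 (−3.30 ± 0.31, adjusted p 7.7e-05; −2.92), KBTBD8 (−1.96, −1.79), FAM111B (−1.28, −1.02), TTR (−1.25, −1.35), RRM2 (−1.25, −1.32), APOA2 (−1.23, −1.21), SNORD60 (−1.20, −0.84), HTR1A (−1.17, −1.02), SNORD12C (−1.16, −1.07) and AFP (−1.14, −0.75). Further genes ranked among the largest on 16 arrays alone, again with 18 arrays first: INHBE (1.58, 2.67), BNC1 (1.35, 2.32), CH25H (1.503, 2.29), CXCL5 (0.78, 2.13), CXCL1 (1.20, 1.88), TAC1 (0.75, 1.88), IL20RB (1.34, 1.88), STMN2 (−0.83, −1.41), HSPA8 (−0.87, −1.19), CST2 (−1.01, −1.18) and CCDC167 (−0.56, −1.11). TXNIP and CST1 had moved the other way between control shRNA and untransduced cells. In TXNIP the group means were 9.37 ± 0.53 untransduced, 7.49 ± 0.10 with the control shRNA and 10.64 ± 0.66 with the KBTBD8 shRNA.

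Lists in pluripotent cells gave a small set of shifts. Cholesterol synthesis lost 5 of 13 members on 18 arrays (9 adjusted over the list alone) and 8 on 16 arrays (10), with DHCR7 (−0.87, −0.77), SQLE (−0.82, −0.77), IDI1 (−0.78, −0.71) and HMGCS1 (−0.64, −0.78). Its camera adjusted p was 2.0e-08 on 18 arrays and 0.029 at an estimated correlation, but 0.095 by the latter on 16 arrays. Endoderm lost 4 of 14 (4 adjusted over the list alone), with APOA1 at −0.67, and the call was lost at an estimated correlation (adjusted p 0.067; 0.032 on 16 arrays, where 6 fell). Histone genes had 3 of 22 that rose on 18 arrays (10 adjusted over the list alone, with 1 that fell) and 10 on 16 arrays, with H2AC13 (0.57, 0.72) and H3C2 (0.39, 0.49), and lost the call at an estimated correlation (adjusted p 0.56). Ribosome biogenesis lost 6 of 53 (9 adjusted over the list alone), with RRP9 (−0.73, −0.52) and NIP7 (−0.67, −0.52), and lost its call too (adjusted p 0.71). Cell cycle lost 5 of 27 and gained 1 (6 and 1 adjusted over the list alone), with PCNA at −0.73 and CCNB2 at 0.51 (estimated adjusted p 0.70), and did not pass on 16 arrays at the preset correlation either (adjusted p 0.14). Hypoxia gained 1 of 18 (1 adjusted over the list alone), VEGFA (estimated adjusted p 0.84), and on 16 arrays its median was 0.0075 and its preset adjusted p 0.97. Targets of FGF-ERK passed at the preset correlation only on 16 arrays (adjusted p 0.025, 5 rose and 1 fell) and not at an estimated one (0.39). The stress response list had 3 members that rose and 1 that fell on 18 arrays (3 and 3 adjusted over the list alone). On 16 arrays 10 rose and 2 fell (10 and 4), with CHAC1 (0.90, 1.78) and TRIB3 (1.03, 1.72), and it passed at both correlations (adjusted p 5.2e-04 and 0.032).

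No member of the neural crest, neural plate, neuron or surface ectoderm lists passed in pluripotent cells on 18 arrays. On 16 arrays 3, 5, 1 and 1 members of these lists fell and none rose, and all their medians turned (crest 0.24 to −0.14, neural plate 0.26 to −0.056, neuron 0.066 to −0.10, surface ectoderm 0.28 to −0.054), with none of them passing camera. Of the fixed set, none passed on 18 arrays, with 16 arrays second: SOX2 (0.40, 0.32), SOX10 (0.34, 0.15), FOXD3 (−0.23, −0.15), TFAP2A (0.81, −0.51), SNAI2 (0.57, −0.095), PAX3 (0.55, −0.43), PAX6 (1.34, −0.15), SOX1 (−0.27, −0.34), TBXT (−0.049, −0.10), SOX17 (−0.28, −0.42), TCOF1 (−0.42, −0.23) and NOLC1 (−0.34, −0.092). On 16 arrays SOX2 rose and PAX3 and SOX17 fell. The signs of TFAP2A, SNAI2, PAX3 and PAX6 on 18 arrays thus rested on the array labelled hESC_shKBTBD8_2. CXCR4 also fell there (−0.68) while showing no change on 18 arrays (0.00).

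Embryoid bodies with the KBTBD8 shRNA lost neural crest genes and gained targets of FGF signalling. SNAI2, PAX3, SOX10, FOXD3 and ETS1, all transcription factors of the crest, fell, and so did the WNT pathway genes DKK1, LEF1 and AXIN2 and the WNT carrier WLS. NR2F1 and MEF2C, which act in crest and craniofacial development, fell as well. DUSP6, ETV5 and IL17RD, which respond to FGF receptors through ERK, rose. On 18 arrays 352 genes changed, 138 higher and 214 lower, 99 of them by 2-fold or more. With only the groups compared 87 genes changed, with a replicate block 187, and with 1 array left out 175 to 333. On 16 arrays 824 changed, 404 higher and 420 lower, and both fits shared 337.

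The 10 largest increases in embryoid bodies, with 16 arrays second, were DUSP6 (1.89 ± 0.31, adjusted p 2.8e-03; 1.56), ETV5 (1.89 ± 0.13, adjusted p 5.5e-07; 1.94), ITGB5 (1.51, 1.09), FAR2 (1.38, 1.10), PKP2 (1.32, 0.99), GPR160 (1.32, 1.27), USP44 (1.26, 0.88), IL17RD (1.23, 1.37), NPR1 (1.22, 1.37) and SEL1L3 (1.21, 1.03). The 10 largest decreases were SNAI2 (−3.31 ± 0.54, adjusted p 2.7e-03; −2.52), NPR3 (−3.25, −3.23), PAX3 (−2.92, −1.95), WLS (−2.86, −1.92), DKK1 (−2.83, −2.20), SCUBE2 (−2.72, −2.60), PRELP (−2.71, −2.48), NR2F1 (−2.70, −2.50), APOA2 (−2.69, −2.67) and MEF2C (−2.66, −2.52). On 16 arrays SIX3 of the forebrain and DLX5 of the placodes led the increases, and none of these passed on 18: SIX3 (1.65, 3.23), DLX5 (0.61, 2.22), HPGD (1.58, 2.19), ADAM28 (1.34, 2.14), SLITRK1 (0.99, 2.03), MECOM (1.11, 2.02), FZD5 (1.21, 2.01), FRZB (0.64, 1.91) and HESX1 (1.17, 1.85). ETS1 (−2.62, −3.19), AFP (−2.56, −2.79) and TTR (−2.52, −2.60) ranked among the largest decreases there.

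**Figure D2:**
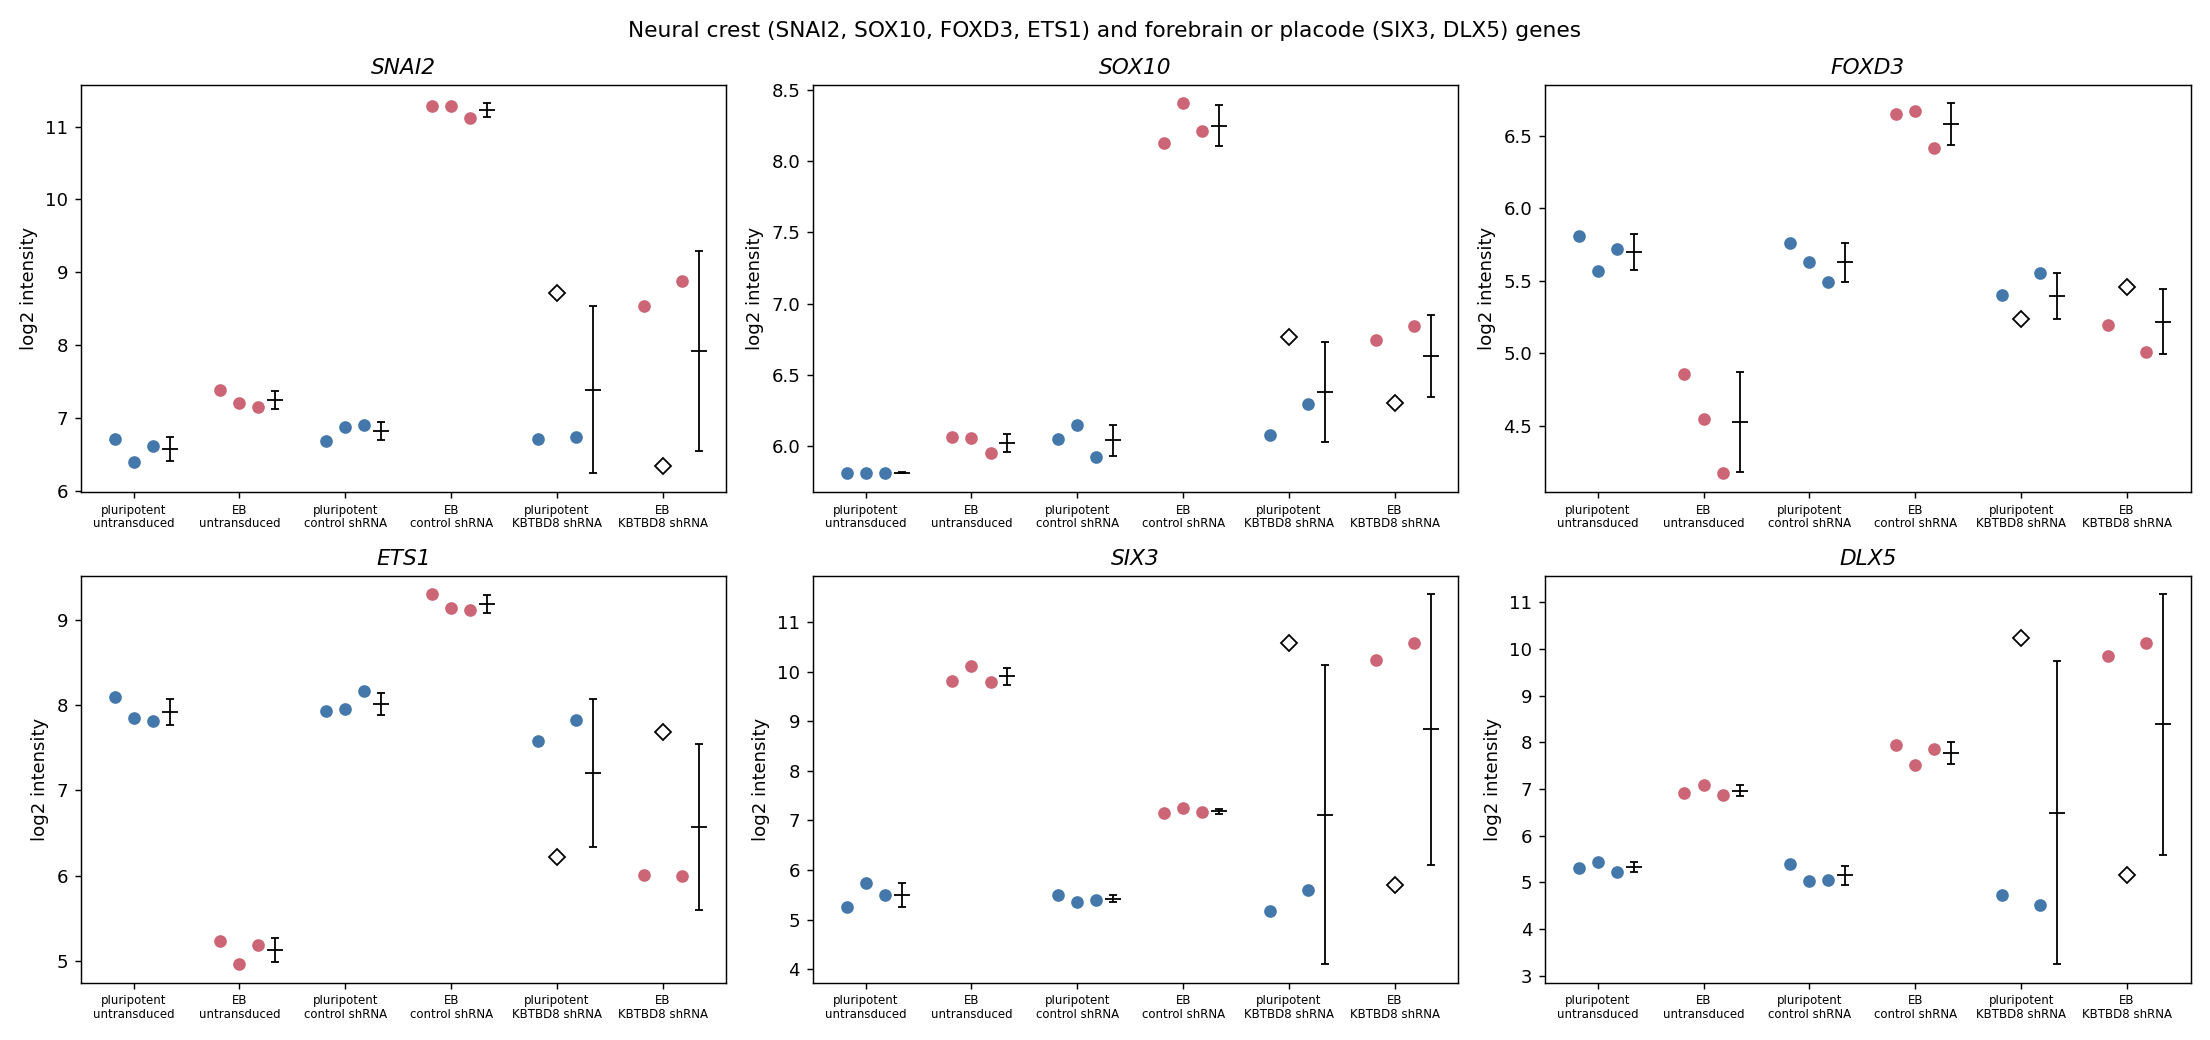
Log2 intensity of 6 genes on each array, by state and treatment. Open diamonds mark both arrays numbered 2 of the KBTBD8 shRNA, and bars show the mean and 1 standard deviation of each group of 3 arrays.

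Of 20 neural crest genes tested in embryoid bodies, 7 fell, 13 did not pass and none rose on 18 arrays (9 fell adjusted over the list alone). On 16 arrays 12 fell and 1 rose (12 and 1 adjusted over the list alone). The median member changed by −0.92 and −0.70, and camera passed at both correlations on 18 arrays (adjusted p 6.1e-13 and 0.025) and on 16 (2.6e-17 and 5.9e-05). SOX10 (−1.62, −1.45) and FOXD3 (−1.36, −1.48) fell in both fits, while TFAP2A (−2.20, −0.86) and TFAP2B (−3.31, −2.14) fell only on 16 arrays. In SNAI2 the group means were 7.25 ± 0.12 in untransduced, 11.23 ± 0.09 in control shRNA and 7.92 ± 1.38 in KBTBD8 shRNA embryoid bodies. In SOX10 they were 6.02, 8.25 ± 0.14 and 6.63 ± 0.29. On 16 arrays the KBTBD8 shRNA means were 8.71 ± 0.24 for SNAI2 and 6.80 ± 0.07 for SOX10. Mean levels of both genes under the KBTBD8 shRNA thus lay between those of untransduced and control shRNA embryoid bodies in both fits.

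Other lists changed with the crest in embryoid bodies. WNT targets lost 4 of 9 (4 adjusted over the list alone) and passed at both correlations (estimated adjusted p 0.031), with LEF1 (−2.42, −1.498), AXIN2 (−1.37, −1.32) and NKD1 (−0.89, −0.94). Endoderm lost 5 of 14 (6 adjusted over the list alone) and also passed at both (estimated adjusted p 0.0056), with AFP, TTR, APOA2 and APOA1 (−1.13, −1.15). Targets of FGF-ERK gained 2 of 14 on 18 arrays (7 adjusted over the list alone) and 7 on 16 (8), with SPRY1 (0.78, 1.10) and SPRY2 (0.75, 1.07), and passed at both correlations (estimated adjusted p 0.0056). Neurons lost 5 of 11 (7 adjusted over the list alone), with STMN2 (−2.10, −1.44), POU4F1 (−0.93, −0.63), ELAVL4 (−0.89, −0.74) and DCX (−0.66, −0.72), and passed at an estimated correlation only on 16 arrays (adjusted p 0.051 and 0.006). Surface ectoderm and placode gained 2 of 13 on 18 arrays (3 adjusted over the list alone), GRHL2 (1.13, 1.05) and CDH1 (0.63, 0.72). On 16 arrays this list gained 10 (10), among them GATA3 (0.21, 0.99) and DLX6 (0.18, 0.75), with an estimated adjusted p of 9.1e-04 (0.38 on 18). Pluripotency gained 2 of 22 (4 adjusted over the list alone), USP44 and SOX2 (0.49, 0.63), and 6 on 16 arrays, CRIPTO (2.61, 1.35) included (estimated adjusted p 0.34 and 0.029). CRIPTO did not pass on 18 arrays.

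Several lists in embryoid bodies passed camera at the preset correlation and lost the call at an estimated one. Mesenchyme and matrix lost 2 of 14 (3 adjusted over the list alone), COL1A2 (−1.05, −0.97) and COL3A1 (−0.71, −0.70; estimated adjusted p 0.17, but 0.032 on 16 arrays). Lateral and cardiac mesoderm lost 2 of 7 (2 adjusted over the list alone), MEF2C and PDGFRA (−1.44, −1.25; estimated adjusted p 0.087). Cell cycle lost 2 of 27 (2 fell and 2 rose adjusted over the list alone), RRM2 (−0.53, −0.44) and TYMS (−0.44, −0.39), although its median was 0.15 (estimated adjusted p 0.47). Hypoxia lost 1 of 18 (1 adjusted over the list alone), EGLN3 (−0.93, −0.82; estimated adjusted p 0.65). Neural plate lost 1 of 24 (2 adjusted over the list alone), FEZF2 (−0.80, −0.65; estimated adjusted p 0.66), and on 16 arrays 7 rose and 3 fell, with LHX2 (0.60, 1.62) among the rises. Cholesterol synthesis had none that passed on 18 arrays (3 rose adjusted over the list alone) and STARD4 (0.40, 0.48) and HMGCS1 (0.11, 0.31) on 16 (estimated adjusted p 0.15). Ribosome biogenesis had none of 53 that passed (0 adjusted over the list alone; estimated adjusted p 0.66), and neither TCOF1 (0.18, 0.06) nor NOLC1 (0.20, 0.03), partners of KBTBD8 in published work, passed. NOTCH targets had none of 11 past the threshold (2 fell adjusted over the list alone; estimated adjusted p 0.18). On 16 arrays hypoxia (adjusted p 0.44, median 0.077), neural plate (0.11), ribosome biogenesis (0.74) and NOTCH targets (0.16) did not pass at the preset correlation either.

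**Figure D3:**
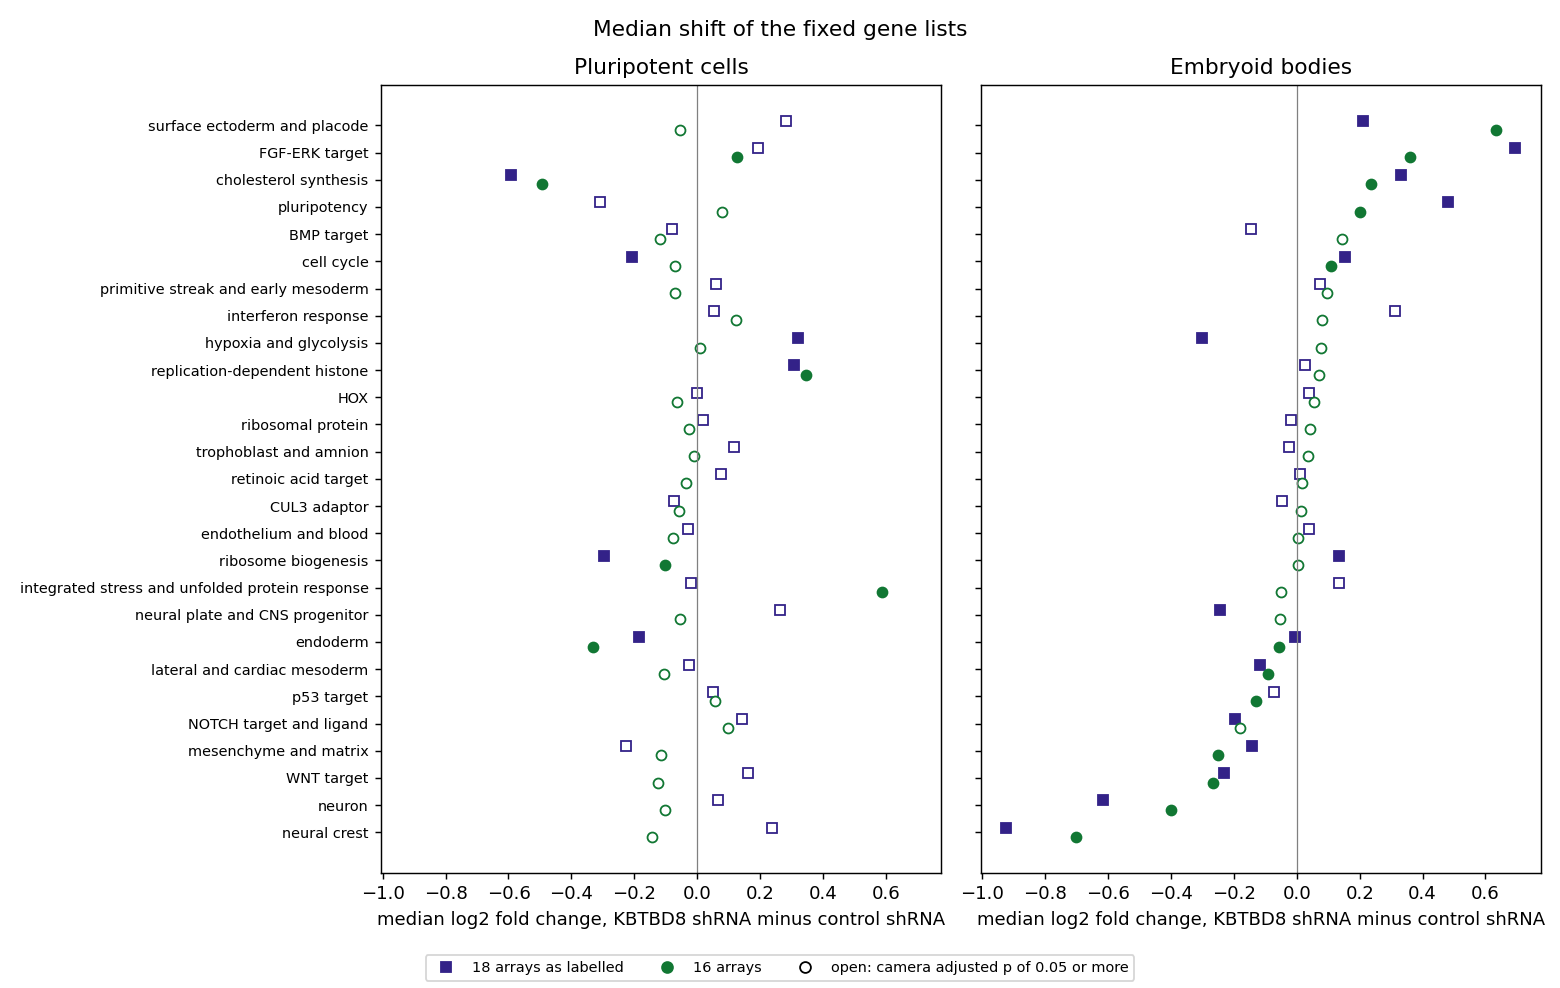
Median log2 fold change of each fixed list, KBTBD8 shRNA minus control shRNA, in pluripotent cells on the left and embryoid bodies on the right. Squares are 18 arrays and circles 16, and filled marks have a camera adjusted p under 0.05 at the preset correlation.

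The remaining lists did not pass camera in embryoid bodies on 18 arrays. Their adjusted p was 0.39 for ribosomal proteins, 0.39 for CUL3 adaptors, 0.39 for primitive streak, 0.48 for endothelium and blood, 0.48 for BMP targets, 0.85 for trophoblast and amnion, 0.78 for HOX genes, 0.56 for histones, 0.084 for p53 targets, 0.092 for the interferon response, 0.25 for the stress response and 0.11 for retinoic acid targets. On 16 arrays p53 targets alone of these passed at the preset correlation, downward (adjusted p 0.0070), and lost the call at an estimated one (0.37). Of the fixed set in embryoid bodies PAX6 (−2.13) did not pass on 18 arrays and fell by 0.55 on 16. SOX1 (−0.21, −0.10), TBXT (0.07, 0.10) and SOX17 (0.00, 0.10) passed in neither fit.

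The effect of the shRNA differed between the states for genes of the crest and of sterol synthesis. At an estimated correlation the crest list lost its call on 18 arrays (adjusted p 0.094) and sterol synthesis kept it (0.025). KBTBD8 was already low in embryoid bodies, so its own positive term is not read as a difference in the action of the shRNA. In control shRNA pluripotent cells the crest genes PAX3 (4.87) and TFAP2A (5.24) were low, against 9.41 and 9.69 in embryoid bodies. A fall of these genes could hardly show in pluripotent cells, so their terms are not read in that way either. ETS1 (8.02, 9.19) was not low. The interaction, which subtracts the pluripotent effect from that in embryoid bodies, called 521 genes on 18 arrays (229 higher, 292 lower) and 1402 on 16 (532, 870), with 466 shared. With only the groups compared it called 240, with a replicate block 161, and with 1 array left out 228 to 579. The largest positive terms were GDF3 (2.57, 1.52), GCNT4 (2.36, 1.59), DUSP6 (2.34, 1.58), KBTBD8 (2.08, 1.80), PRDM14 (1.98, 1.40), CST1 (1.90, 1.38), EEIG2 (1.88, 1.11), B3GALT1 (1.75, 1.59), ITGB5 (1.72, 0.87) and PDPN (1.70, 1.03). The largest negative terms were SNAI2 (−3.88, −2.43), WLS (−3.76, −1.95), TXNIP (−3.31, −4.03), KRTAP21-1 (−3.17, −2.33), NPR3 (−3.14, −3.00), NR2F1 (−2.94, −2.40), CDH9 (−2.91, −1.51), SCRG1 (−2.80, −2.32), MEF2C (−2.75, −2.48) and HDC (−2.75, −2.21). On 16 arrays the positive terms were led by the same SIX3 and DLX5, and none of these passed on 18: SIX3 (−0.04, 3.27), DLX5 (−0.73, 2.75), SLITRK1 (0.43, 2.58), FZD5 (0.88, 2.49), HPGD (1.09, 2.35), HESX1 (1.06, 2.34), MECOM (0.37, 2.01), GAD2 (1.08, 1.90), FRZB (−0.69, 1.89) and VAX1 (0.94, 1.88). Among its negative terms were NRIP3 (−2.26, −3.08), ARRDC4 (−1.67, −2.99), ETS1 (−1.81, −2.87), INHBE (−0.36, −2.80), BNC1 (−0.71, −2.65), ITGA4 (−2.59, −2.63) and SCUBE2 (−2.73, −2.44).

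Of the fixed set the interaction passed for SOX10 (−1.96, −1.60), FOXD3 (−1.13, −1.32) and SNAI2, and on 16 arrays for PAX3 (−3.46, −1.52) and SOX17 (0.27, 0.52). It did not pass for TFAP2A (−3.01, −0.35), PAX6 (−3.46, −0.41), TCOF1 (0.60, 0.29), NOLC1 (0.54, 0.13), SOX2 (0.09 on 18 arrays), SOX1 (0.06) or TBXT (0.12). Cholesterol synthesis had 5 of 13 members with a positive term on 18 arrays (9 adjusted over the list alone) and 10 on 16, with DHCR7 (1.42, 1.31), SQLE (1.17, 1.10) and, on 16 arrays alone, HMGCS1 (0.75, 1.09), and was the only list on 18 arrays to pass at both correlations (adjusted p 9.4e-09 and 0.025). Neural crest had 5 of 20 negative (8 adjusted over the list alone) and lost the call at an estimated correlation (adjusted p 0.094; 0.0056 on 16 arrays, where 10 were negative). Of all lists 13 passed at the preset correlation on 18 arrays and 13 on 16, of which 5 also passed at an estimated one.

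Both KBTBD8 comparisons shared few genes. Across genes they correlated at −0.18 on 18 arrays and 0.03 on 16, with 9 shared rises (3.17 if independent), 18 shared falls (6.07) and 13 opposite changes. On 16 arrays the shared rises were 54 (34.1), the shared falls 51 (23.4) and the opposite changes 75. Untransduced differentiation correlated with the effect of the shRNA in embryoid bodies at −0.54 on 18 arrays but −0.14 on 16. Genes that rose in untransduced differentiation had a median of −0.31 in that contrast and those that fell 0.45 on 18 arrays, and −0.08 and 0.10 on 16. Neither shift held at an estimated correlation (p 0.23 on 18 arrays, 0.262 on 16).

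Probe sets without exactly 1 gene symbol were few among the changes. Of 6928 such probe sets tested, 13 changed in pluripotent cells on 18 arrays, 5 of them higher, and 23 changed in embryoid bodies, 4 higher. On 16 arrays 114 and 37 changed, 69 and 16 of them higher.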

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

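In this part the tests of the out-of-place arrays, of a shift common to both states and of the low KBTBD8 level were chosen only after the result was seen; quantile scaling and the regroupings were fixed earlier.

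Both arrays numbered 2 of the KBTBD8 shRNA lay with the state opposite to their label, and they fit an exchange of the 2 labels, since 2 of 2 correlated best with the KBTBD8 shRNA group of the other state. A mixed or partly differentiated culture was excluded for the array labelled hESC_shKBTBD8_2, which stood at 0.971 on a scale from the pluripotent (0) to the embryoid body (1) mean of its treatment. A complete change of state in both cultures could not be told from an exchange, as the array labelled EB6_shKBTBD8_2 stood at 0.0159 on that scale. A biological cause would need pluripotent cells to differentiate fully and embryoid bodies to stay undifferentiated at once. An exchange may have happened at any step from culture to label, and only the submitters' records could show which.

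Neural crest genes were higher in control shRNA than in untransduced embryoid bodies. The list kept a camera adjusted p of 6.83e-09 after quantile normalization. That test could not decide about scaling, because camera compares the list with all other genes, which a common scaling would move alike. Array medians were 5.85 to 5.95 untransduced and 5.97 to 6.12 transduced. A scaling difference common to all genes was thus small against the list median of 1.92. A shift of array batch common to both states was not excluded for the whole list. The list differed between the states with a camera adjusted p of 4.85e-10 in the added comparison. At an estimated correlation that p was 0.12 on 18 arrays and 3.8e-05 on 16. In untransduced pluripotent cells PAX3 (4.47) and TFAP2A (4.69) lay below the 40th percentile, where a shift may not show. SNAI2 (6.57 untransduced, 6.82 control shRNA) and ETS1 (7.92, 8.02) lay above it and moved little, which argues against a common shift for these genes. Also left open are a separate differentiation run for the transduced cells and a biological effect of transduction or selection on cell fate. Either could act alone or with the other. No array here separates them, so the KBTBD8 shRNA is best compared with the control shRNA.

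KBTBD8 was not lower under its shRNA in embryoid bodies. A level at the floor of measurement fits, since KBTBD8 lay below the 40th percentile on 9 of 9 arrays labelled embryoid body, between the 20.4 and the 36.1 percentile. Its values there still spread from 4.07 to 5.12 and so do not show a fixed floor. The highest was on the array labelled EB6_shKBTBD8_2, which lay with the pluripotent arrays, and the next was 5.06 on an untransduced array. A loss of shRNA activity during differentiation could not be told apart, as the difference of 0.12 is what either would give. A biological explanation is that differentiation itself lowers KBTBD8 to a level at which the shRNA makes little further difference, so that the crest change may stem from the pluripotent stage or the first days of culture.

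The interaction of the shRNA with state called 521 genes on 18 arrays. Both out-of-place arrays enter this term, so part of it may be the difference between the states themselves. Across genes its values correlated at 0.55 with those on 16 arrays, where 1402 genes were called and 466 were shared. The term of KBTBD8 itself is not read as a difference in the action of the shRNA, since its level was already low in embryoid bodies. The named terms were GDF3 2.57, GCNT4 2.36, DUSP6 2.34, KBTBD8 2.08, PRDM14 1.98, CST1 1.90, EEIG2 1.88, B3GALT1 1.75, ITGB5 1.72 and PDPN 1.70 above zero. Below zero they were SNAI2 −3.88, WLS −3.76, TXNIP −3.31, KRTAP21-1 −3.17, NPR3 −3.14, NR2F1 −2.94, CDH9 −2.91, SCRG1 −2.80, MEF2C −2.75 and HDC −2.75. List medians of this term were 0.75 for pluripotency, −1.04 for neural crest, −0.28 for neural plate, −0.68 for neuron, −0.033 for endoderm, 0.51 for ribosome biogenesis, 0.42 for cell cycle, 0.78 for cholesterol synthesis, −0.65 for hypoxia, −0.39 for WNT targets, −0.34 for NOTCH targets, 0.42 for FGF-ERK targets and −0.19 for histones. These 13 lists passed camera at the preset correlation on 18 arrays, and only cholesterol synthesis did at an estimated one. The neural plate and hypoxia medians changed sign on 16 arrays (0.24 and 0.085).

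The effect of differentiation differed between control shRNA and untransduced cells in 744 genes, a comparison added after the data were seen. Its list medians were 1.55 for neural crest, 0.42 for neuron, 0.86 for surface ectoderm, 0.20 for lateral and cardiac mesoderm, 0.31 for endoderm, 0.33 for trophoblast, −0.20 for ribosome biogenesis, −0.32 for CUL3 adaptors, 0.33 for p53 targets, −0.27 for cell cycle, 0.41 for the stress response, −0.25 for cholesterol synthesis, 0.52 for hypoxia, 0.28 for WNT targets, 0.36 for BMP targets and 1.18 for retinoic acid targets. These 16 lists passed camera at the preset correlation on 18 arrays and 0 did at an estimated one, where 11 lists passed on 16 arrays. Of named crest genes SNAI2 (3.73), PAX3 (4.15), FOXD3 (2.12) and SOX10 (1.996) passed, and TFAP2A (2.90, adjusted p 0.30) and KBTBD8 itself (−0.32) did not. Probe sets without exactly 1 gene symbol that were higher under the KBTBD8 shRNA numbered 5 in pluripotent cells and 4 in embryoid bodies, and their identity was not examined.

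Regrouping the arrays gave 10 splits for each comparison of 2 groups, which are too few for a share under 0.05. The real grouping reached 5491 genes for untransduced differentiation, 4810 for control shRNA differentiation, 729 and 352 for the KBTBD8 shRNA in pluripotent cells and embryoid bodies, and 1713 and 3850 for control shRNA against untransduced cells. In each of these 1 of 10 splits, the real one, reached that count, and the highest other gave 0. For KBTBD8 shRNA differentiation 10 of 10 splits reached the real count of 0, and the highest gave 6891. That highest split exchanges both arrays numbered 2 and reflects the structure of the samples. The interaction's 521 genes were reached by 1 of 100 regroupings, the real one, with 421 for the highest other. That other one exchanges all 3 pluripotent labels and 0 embryoid body labels, so it still holds real shifts. The real grouping also holds both out-of-place arrays, so these regroupings could not decide about chance. The added comparison's 744 genes were reached by 9 of 100, the highest giving 4704. That highest regrouping also exchanges all 3 pluripotent labels and so adds both shifts instead of subtracting them. For this comparison too, the regroupings could not decide about chance.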

How the results depend on the processing

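The alternatives without both doubted arrays and the added comparison were chosen only after the result was seen; in all that follows the cause was not tested. Quantile normalization, a floor at the 20th percentile, a variance trend with robust fitting, the mean of probe sets and all probe sets moved no count of the 25 comparison results by more than 1.5-fold and reversed no direction. Without a filter the correlation of both differentiation contrasts was 0.75, and with a filter at the 60th percentile 0.78. Median centring left 428 genes for the KBTBD8 shRNA in pluripotent cells and 277 for the interaction. A 2-fold minimum left 1274 genes for untransduced differentiation, 1007 for control shRNA differentiation, 37 and 99 for the KBTBD8 shRNA in pluripotent cells and embryoid bodies, 155 for the interaction, 68 and 499 for control shRNA against untransduced cells, and 318 for the added comparison.

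Fitting only the groups compared called 0 genes in pluripotent cells, where KBTBD8 (−1.96) had an adjusted p of 0.0938, then 87 in embryoid bodies, 240 in the interaction, 2644 and 7046 for control shRNA against untransduced cells, and 2279 for the added comparison. A replicate block gave 310 genes in pluripotent cells, 187 in embryoid bodies, 161 in the interaction and 473 in the added comparison. For arrays paired by number, no comparison had all correlations above 0.1. They were −0.13, −0.01 and −0.07 for untransduced and −0.17, −0.14 and 0.05 for control shRNA differentiation, so the number is not evidence of a shared culture there. In the KBTBD8 shRNA groups the out-of-place arrays enter the group means. Correlations there (for the shRNAs in pluripotent cells −0.07, −0.10 and 0.33) could thus not decide.

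Array weights did not converge and gave 11.7 to the array labelled hESC_shKBTBD8_1 against 0.0935 and 0.104 to the doubted arrays. They called 8226 genes for control shRNA differentiation, 7178 for KBTBD8 shRNA differentiation, 5706 and 1040 for the shRNA in pluripotent cells and embryoid bodies, 2869 for the interaction, 4557 and 7590 for control shRNA against untransduced cells, and 3253 for the added comparison. Correlations were 0.75 between both differentiation contrasts, 0.087 between both KBTBD8 contrasts and −0.20 between untransduced differentiation and the shRNA in embryoid bodies. Medians were −0.084 for neural plate and 0.018 for hypoxia in embryoid bodies, and 0.057 for neural plate and −0.65 for the stress response in the interaction. Interaction terms were SIX3 3.22, DLX5 2.32, FRZB 1.92, LHX2 1.61 and GATA3 1.47, and CXCR4 in pluripotent cells was −0.80.

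Leaving out both doubted arrays called 5465 genes and 11 lists for KBTBD8 shRNA differentiation, 1991 and 824 genes for the shRNA in pluripotent cells and embryoid bodies, 1402 for the interaction, 4132 and 6370 for control shRNA against untransduced cells, and 2398 for the added comparison. Correlations were 0.027 between both KBTBD8 contrasts and −0.14 between untransduced differentiation and the shRNA in embryoid bodies. Among lists with a call in either fit, signs reversed for the medians of neural plate (0.24), ribosomal proteins (0.066), stress response (−0.75), hypoxia (0.085) and surface ectoderm (0.61) in the interaction, for the stress response (0.59) in pluripotent cells and for hypoxia (0.077) in embryoid bodies, where neural plate was −0.052. Among genes named in the report with a call in either fit they reversed for SIX3 (3.27), DLX5 (2.75), FRZB (1.89), LHX2 (1.69) and GATA3 (1.41) in the interaction and for PAX3 (−0.43) and CXCR4 (−0.68) in pluripotent cells. With a replicate block as well, the counts were 5462 genes and 11 lists, 1636, 728, 1333, 4202, 6409 and 2368, in the same order. With that replicate block the correlations were 0.039 and −0.14, the medians −0.12 for crest in pluripotent cells, −0.050 and 0.063 for neural plate and hypoxia in embryoid bodies, and 0.24, −0.75 and 0.085 for neural plate, stress response and hypoxia in the interaction. SIX3 (3.27), DLX5 (2.75), FRZB (1.89), LHX2 (1.69), GATA3 (1.41), PAX3 (−0.46) and CXCR4 (−0.67) kept those signs under the replicate block.

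With an estimated correlation the lists that passed were 0 for each of the 3 differentiation comparisons, 1 and 4 for the KBTBD8 shRNA in pluripotent cells and embryoid bodies, 1 for the interaction, 1 and 1 for control shRNA against untransduced cells, and 0 for the added comparison. The genes of untransduced differentiation had medians of −0.31 and 0.45 in embryoid bodies with a p of 0.23. The rotation test fry passed 12, 17 and 0 lists for the 3 differentiation comparisons and gave those medians (−0.31, 0.45) a p of 0.134. On 16 arrays with an estimated correlation 3 and 6 lists passed for untransduced and control shRNA differentiation, 2 and 8 for the shRNA in pluripotent cells and embryoid bodies, 5 for the interaction, and 1 and 6 for control shRNA against untransduced cells. Those arrays gave −0.082 and 0.10 for the differentiation genes (p 0.262), with medians of −0.052 and 0.077 for neural plate and hypoxia in embryoid bodies and 0.24, −0.75 and 0.085 for neural plate, stress response and hypoxia in the interaction.

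Leaving out each array in turn gave 294 to 657 genes for the shRNA in pluripotent cells, 175 to 333 in embryoid bodies, 228 to 579 in the interaction, 856 to 1363 and 2446 to 3044 for control shRNA against untransduced cells, and 471 to 733 for the added comparison. KBTBD8 shRNA differentiation ranged from 1 to 11 lists. Correlations ranged from 0.74 to 0.77 for both differentiation contrasts, from −0.31 to 0.22 for both KBTBD8 contrasts and from −0.63 to −0.14 for untransduced differentiation against the shRNA in embryoid bodies. Medians ranged from 0.11 to 0.87 for neural plate under KBTBD8 shRNA differentiation, and in embryoid bodies from −0.36 to −0.052 for neural plate and from −0.57 to 0.077 for hypoxia.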

Other observations

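In this part the use of 16 arrays was chosen only after the result was seen, whereas both extra lists and their predicted direction were written before the values of their genes in the comparison were read.

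The control shRNA group stood apart from both other treatments for some genes and lists. TXNIP was lower under the control shRNA than in untransduced pluripotent cells (−1.88) and higher under the KBTBD8 shRNA than under the control (3.15), and DDIT4 (−1.64, 1.94) did the same. CST1 went the other way (3.67, −3.30), and so did APOA2 (1.70, −1.23), AFP (1.68, −1.14) and TTR (1.55, −1.25). In embryoid bodies AFP (3.71, −2.56), APOA2 (3.26, −2.69), SNAI2 (3.98, −3.31), PAX3 (4.55, −2.92) and SOX10 (2.22, −1.62) followed the same pattern. The 4 lists that passed at both correlations under the KBTBD8 shRNA in embryoid bodies on 18 arrays also went opposite ways. From untransduced to control shRNA 14 of 20 crest, 7 of 14 endoderm and 5 of 9 WNT members rose. In the same lists 0, 1 and 1 fell. From control shRNA to KBTBD8 shRNA 7, 5 and 4 fell and none rose. FGF-ERK targets first had 5 of 14 that fell and 2 that rose, without passing camera, and then 2 that rose. For these genes and lists both contrasts share the control shRNA arrays, so part of the opposite signs could come from those arrays alone. SNAI2 (−2.52) and PAX3 (−1.95) kept their sign on 16 arrays. Groups with a further control shRNA or another shRNA against KBTBD8 were not analysed here, and only these would separate the target from the vector.

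Stress genes that rose in pluripotent cells led to a hypothesis, that lower KBTBD8 brings on an ATF4 response. A list of 21 further ATF4 targets was written before the values of its genes in this comparison were read. On 16 arrays 16 rose and none fell, with a median of 0.47 and a camera p of 2.23e-14 (0.00102 at an estimated correlation). STC2 (1.30), NUPR1 (0.96), CEBPG (0.71), CARS1 (0.68) and AARS1 (0.64) were among them. The list therefore fits a wider rise of ATF4 targets on those arrays. The hypothesis came from the same arrays, so this is not independent support. Nor can the list tell whether lower KBTBD8 was the cause. On all 18 arrays it did not pass (p 0.346, 1 rose, median −0.01). TXNIP and ARRDC4 respond to glucose and amino acid supply, so a difference in medium or density between cultures may give the same picture as a fall in KBTBD8. A rescue with shRNA-resistant KBTBD8, with ATF4 protein measured, would decide between them.

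Placode and forebrain genes that were higher in embryoid bodies on 16 arrays led to another hypothesis, of wider anterior neural expression in place of the crest. The control shRNA was low for some of them. SIX3 averaged 9.90 in untransduced, 7.18 in control shRNA and 10.41 in KBTBD8 shRNA embryoid bodies on 16 arrays. Most of its rise thus regained the untransduced level, and the rest went above it. LHX2 was lower in control shRNA than in untransduced embryoid bodies (−2.96), so its rise went towards the untransduced level. DLX5 (6.96, 7.77 and 9.99) also went above both other groups. A list of 14 anterior neural genes was written, of which RAX, SIX6, OTX1, OTX2, EMX2 and LHX5 also belonged to the neural plate list whose summary had been seen, and EMX2 had been read in another comparison. On 16 arrays its camera p was 0.111 (0.163 at an estimated correlation), with 3 that rose, 2 that fell and a median of 0.17. RAX (0.81), SIX6 (0.70) and SP8 (0.66) rose, and EMX2 (−0.80) and OTX1 (−0.61) fell. On 18 arrays the p was 0.884. The prediction written beforehand counted any p of 0.05 or more against the hypothesis, which was too strict, because a p that misses shows no absence and the members went both ways around a median of 0.17. The predicted rise of the set was thus not seen, a rise of every member is excluded by EMX2 and OTX1, and a rise of some anterior genes may still hold. Single-cell profiles of the embryoid bodies could show whether cells changed fate or their proportions moved.

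A further hypothesis, untested here, is a change in the balance of FGF and WNT signals, both of which induce crest. ETV5 and DUSP6 were higher and LEF1, AXIN2 and DKK1 lower in embryoid bodies, whereas SPRY1 (0.78, 1.10) and SPRY2 (0.75, 1.07) passed only on 16 arrays and 2 of 14 FGF-ERK targets passed on 18. With an estimated correlation 4 lists passed in embryoid bodies on 18 arrays (crest, endoderm, WNT and FGF-ERK), and 8 did on 16. WNT targets had moved the other way from untransduced to control shRNA embryoid bodies on 18 arrays. There 5 of 9 rose and 1 fell (camera adjusted p 0.010, 0.28 at an estimated correlation). FGF-ERK targets had 5 of 14 that fell and 2 that rose there (camera adjusted p 0.0996). Both contrasts share the control shRNA arrays, so the WNT and FGF changes could come partly from those arrays. Whether the signals likely changed the fate or the fate changed the signals cannot be read from a single day. Levels of KBTBD8 protein and a series of days would be needed, and neither was analysed here.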
